A study of Mus musculus with 4 samples.

How the data were processed

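Polyadenylated RNA from cultured mouse satellite cells, the stem cells of skeletal muscle, was sequenced in 4 samples. Per the labels, the cells came from the hindlimb of C57BL/6 mice, grew in F10 medium with 10% HS, and were harvested 48 h after siRNA treatment. The labels put 2 samples in the LncMyoD knockdown group and 2 in the control siRNA group, by title, description and treatment tag. The treatment protocol of the control samples, however, carries the same text as that of the knockdown samples and names LncMyoD as the target. Nothing in the labels says whether replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

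Per the labels' protocols, cDNA was made with the SMART-Seq v4 kit, sheared and built into libraries with the Ovation Ultralow system, and sequenced on a NextSeq 500 as paired reads of 150 nt. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 1.3, StringTie 1.3.3 and the mouse build mm10, without their roles or order. The annotation release and any strand setting are not given in the sources used here. Amplified full-length cDNA and a transcript-level assignment of fragments can both move the value of a gene whose exons are shared with another gene or whose transcripts differ in length.

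The deposited table holds one FPKM value (fragments per kilobase of transcript, scaled to the fragments mapped) per gene and sample, made by the authors; the unit was read from the values. The 4 columns summed to between 317223 and 322496, not to the fixed total of TPM. In genes with 1 exon and 1 transcript, FPKM multiplied by transcript length fell on whole multiples of a step of 0.162 to 0.182, within a tolerance of 0.1 of a step, for 98.7% to 99.5% of 742 to 795 values per library, where chance gives 20.0%. That step gives the relative depth of the libraries, with a ratio of 1.12 between the deepest and the shallowest. An FPKM of 1 on a transcript of 1 kb then rests on 36.7 to 41.1 reads of 150 nt. Since reads were spread over bases and no whole read counts were recovered for genes with several transcripts, no count model was used.

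The table had 54446 rows, of which 29477 were at 0 in every sample. Gene symbols were taken from the table. Coordinates, exons, transcript lengths and GC content came from GENCODE M21 on GRCm38, the assembly behind mm10, in which 54409 of the identifiers were found and 37 were not. There were 93 symbols on more than 1 row, and these rows were kept apart by identifier.

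The 10900 genes with a mean of at least 1 FPKM over the 4 samples were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are knockdown minus control on the log2(FPKM + 1) scale, which understates changes of low genes. The fit had 2 residual and 4.09 prior degrees of freedom. The median standard error was 0.198, and the median half-width of the 95% interval was 0.48. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for library summaries and plots.

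Before the data were examined, 28 gene lists were fixed for muscle stem cells, siRNA treatment and other cell types of hindlimb preparations. The 24 lists with at least 5 tested members were compared with all other genes by camera, with a preset inter-gene correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move on balance one way and, in a mixed form, whether they change in either direction. Single genes adjusted over a list alone were adjusted among its members, with no correction across the 24 lists. The fixed rule for named genes took LncMyoD and 10 genes always named; per direction, up to 10 genes with a mean of at least 5 FPKM in the higher group and no overlap between groups, by size of change among those past the threshold and then by unadjusted p; and per list, up to 4 members past the threshold or else the 2 with the lowest p. Of the genes this rule names, 1 is not reported here. The second Ptp4a1 row, the lincRNA 1700025L06Rik and further genes given as single values were chosen after their values were seen.

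The steps were tested on simulated data drawn from the fitted means and spreads of the 10900 genes. In 20 runs with 200 changed genes, the fit recovered 3.21% of changes of 1.5-fold, 34.4% of 2-fold and 85.7% of 4-fold, and 5.27% of its calls were false. A list of 45 genes shifted by -0.2 was found by camera in 100% of runs with the preset correlation and in 50% with an estimated one. Unshifted lists whose members shared a library effect with an SD of 0.15 were called in 59% of cases with the preset correlation and in 4.75% with an estimated one.

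The alternatives fixed in advance were a replicate block, quantile normalization, scaling by median ratios, no filter, a filter at a mean of 5 FPKM, limma without the trend, a pseudocount of 0.1, an added threshold of 1 on the absolute log2 fold change, each sample left out in turn, the other list tests, and lists without shared members. Summing rows that share at least 50% of the exonic bases of the shorter row, which merged 4011 rows, and removing trends with transcript length, GC content and level were chosen after seeing the data. No sample was left out of the reported fit.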

Results

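The data were transcript levels of cultured mouse satellite cells given siRNA against LncMyoD, a long non-coding RNA named for its neighbour Myod1, or control siRNA, with 2 samples per group. The knockdown libraries had 10952 and 11090 rows at 1 FPKM or more, and the control libraries had 10751 and 10761. Mitochondrially encoded genes took 3.12% and 2.74% of all FPKM in knockdown replicates 1 and 2, and 3.24% and 3.16% in the controls. Correlations of log2 values across genes, which are not independent replicates, were 0.972 within knockdown, 0.979 within control, and 0.971 to 0.975 between the groups.

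The first question was whether the targeted transcript was lower. Of the deposited rows, 0 carried the name LncMyoD. The fixed rule then asked for the values of any row between Myod1 (chromosome 7, 46376474 to 46379099, plus strand, GRCm38) and Kcnc1, and 0 rows lay there. That interval lies downstream of Myod1 only, so its lack of rows does not show whether the target has a row elsewhere. The level of the target was not analysed here, and the knockdown labels have no such check. The treatment protocol of the control samples also names LncMyoD as the target, so each comparison of knockdown with control rests on the titles, descriptions and treatment tags. The nearby lincRNA 1700025L06Rik (chromosome 7, 46345771 to 46349373, minus strand), 27100 bases upstream of Myod1 and chosen after the data were seen, had 2.01 and 0.615 FPKM in knockdown and 3.12 and 2.17 in control, a log2 fold change of -0.71 ± 0.35 (SE) with an adjusted p of 0.717. Its log2 fold change was -1.16 and -0.26 without knockdown replicates 1 and 2. This lincRNA is not claimed to be LncMyoD.

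The second question was which genes differed between knockdown and control cells. At the adjusted threshold, Pttg1ip, which codes for a binding partner of securin, was the 1 gene called higher. Gm15564, Gm21982, a row of Ptp4a1, Ntmt1 and Tpm4 were the 5 called lower. Pttg1ip stood at 80.7 ± 2.87 FPKM in knockdown against 11.1 ± 0.234 in control (SD, n = 2), a 7.28-fold difference. Tpm4, a tropomyosin of actin filaments, was the most abundant of the 6 and stood at 450.4 ± 13.7 FPKM against 842 ± 27.9 (SD, n = 2). Ntmt1, an N-terminal protein methyltransferase, stood at 7.08 ± 0.440 FPKM against 29.7 ± 1.01 (SD, n = 2).

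By limma, the log2 fold change of Pttg1ip (chromosome 10, 77581720 to 77598732, plus strand) was 2.76 ± 0.11 (SE), with an adjusted p of 0.00285. Ntmt1 (chromosome 2, 30807826 to 30823033, plus strand) fell by 1.92 on the log2 scale (SE 0.14, adjusted p 0.0166). Tpm4 (chromosome 8, 72134975 to 72153142, plus strand) fell by 0.90 (SE 0.076, adjusted p 0.0350). The annotated transcripts of these coding genes range from 351 to 2294 bases for Pttg1ip, 445 to 1387 for Ntmt1 and 359 to 2128 for Tpm4. The non-coding Gm15564 (chromosome 16, 35966752 to 35983230, minus strand) is annotated as antisense, and no strand setting is given for the values. It had 14.2 and 15.9 FPKM in control and 0.115 in knockdown replicate 1. In knockdown replicate 2 it was listed at 0, and its limma adjusted p was 0.00450.

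The other 2 lower rows share exons with further rows. Gm21982 (chromosome 7, 30641001 to 30664937, minus strand) had 0.179 and 0.171 FPKM in knockdown against 13.1 and 13.4 in control (adjusted p 0.00450), and 94.3% of its exonic bases are shared with Rbm42 and Haus5. With these rows summed the log2 fold change was -0.04 (limma adjusted p 0.963), in a range of 0.00409 to 0.963 over its alternatives. A change in Gm21982 alone would give -0.24 in that sum, within its 95% interval of -0.40 to 0.32. The sum therefore cannot tell whether Gm21982 fell. Ptp4a1, a protein tyrosine phosphatase, occupies 2 rows. The row ENSMUSG00000026064 (chromosome 1, 30940302 to 30949309, minus strand) fell by 2.87 on the log2 scale (SE 0.21, adjusted p 0.0166), while ENSMUSG00000117310 had a log2 fold change of 0.88 ± 0.18 (SE) with an adjusted p of 0.523. The sum of both Ptp4a1 rows had a log2 fold change of 0.10 (95% interval -0.21 to 0.42).

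**Figure D1:**
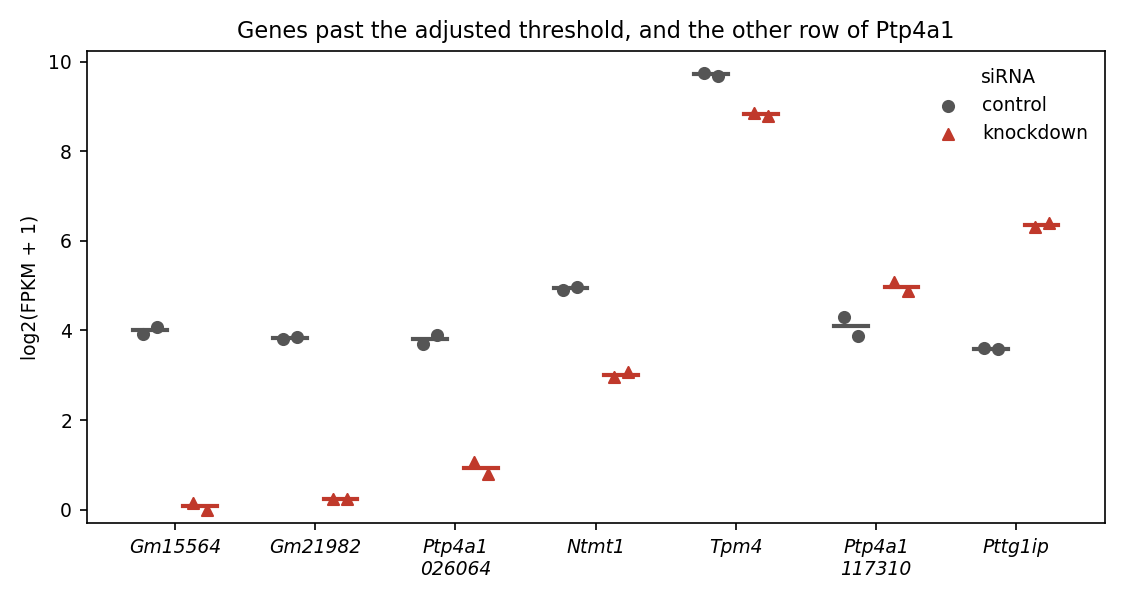
Levels of the 6 genes past the adjusted threshold and of the second Ptp4a1 row, as log2(FPKM + 1) on the vertical axis, with each point a library and each line a group mean. Pttg1ip lies higher in both knockdown libraries, the 5 lower rows lie below both controls, and the rows of Ptp4a1 move in opposite directions.

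At an unadjusted p under 0.05 there were 772 genes, 478 higher and 294 lower, where chance gives 545. That count was 1150 and 1158 without knockdown replicates 1 and 2, and 405 and 526, below the chance value, without control replicates 1 and 2. Both knockdown libraries lay above both controls for 22.1% of genes and below for 16.3%, where chance gives 16.7% in each direction. These values were not rescaled between libraries. The median log2 fold change of all genes tested was 0.026, and the median ratio factor was 1.03 in knockdown replicate 2 and 0.996 in both controls. More genes rising than falling was not told apart from such an offset. Leaving out 1 library and assuming that the lone sample varies like the other group, Ptp4a1 and Ntmt1 had adjusted p-values of 0.0767 and 0.0628 without knockdown replicate 2, 0.0713 and 0.0782 without control replicate 1, and 0.0931 and 0.110 without control replicate 2, and Tpm4 had 0.340 and 0.358 without control replicates 1 and 2. By limma without the trend, Tpm4 had an adjusted p of 0.596 and Ntmt1 0.0879. No gene passed without the filter on low values, where the adjusted p of Pttg1ip was 0.147.

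The genes next in order by unadjusted p did not pass the adjusted threshold. On the higher side, Nfe2l1, a transcription factor of proteasome genes, had 13.0 and 17.7 FPKM against 2.28 and 2.56, a log2 fold change of 2.24 with an adjusted p of 0.0511. Clu, an extracellular chaperone, had 14.9 and 16.4 FPKM against 4.59 and 5.17 (adjusted p 0.105), and the zinc finger gene Zfp568 had a log2 fold change of 2.27 (adjusted p 0.116). The values were 0.73 for Lox, 0.66 for Thbs1, 1.00 for Adam10, 0.78 for Grb10, 0.54 for Anxa1 and 0.82 for Srprb, with adjusted p-values from 0.235 to 0.265. On the lower side, the log2 fold changes were -1.21 for Vkorc1, -0.62 for Nup62, -0.81 for Cirbp, -1.12 for Rgs4 and -0.61 for Uqcrfs1, with adjusted p-values of 0.235 for Vkorc1 and 0.265 for the others.

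The regulators of the muscle lineage did not pass the test. Myod1, the neighbour of the target, stood at 625 ± 59.1 FPKM in knockdown against 694 ± 4.53 in control (SD, n = 2), a log2 fold change of -0.15 with a 95% interval of -0.37 to 0.06, and of -0.06 and -0.25 without knockdown replicates 1 and 2. Myog, a factor of differentiating myoblasts, stood at 3100 ± 434 against 4063 ± 188 (SD, n = 2), a log2 fold change of -0.40 with an adjusted p of 0.607, and of -0.25 without knockdown replicate 2. Myf5 had 6.11 and 7.31 FPKM in knockdown against 8.20 and 7.63 in control, a log2 fold change of -0.21 with an adjusted p of 0.821, and of -0.10 and -0.33 without knockdown replicates 1 and 2. Mef2c had 1.39 and 0.659 FPKM against 1.13 and 1.69, a log2 fold change of -0.26 with an adjusted p of 0.868. Its value was -0.53 and -0.0033 without knockdown replicates 1 and 2, and -0.43 and -0.10 without control replicates 1 and 2. Pax7, the satellite cell factor, had 1.40 and 0.625 FPKM in knockdown and 1.02 and 0.859 in control, below the filter and not tested. The list of myogenic regulators had a median log2 fold change of -0.03 over 22 members, with 11 negative and 11 positive and a camera adjusted p of 0.339, and its member Msc had -0.51. The list median was -0.0063 and -0.09 without knockdown replicates 1 and 2, and 0.0056 and -0.06 without control replicates 1 and 2.

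Sarcomere genes, which code for the contractile apparatus, fell as a list, with a median log2 fold change of -0.22 over 45 members and 41 of them negative (camera adjusted p 4.53e-09). The adjusted p was 0.583 with an estimated correlation. In 22 members both knockdown libraries lay below both controls, but 0 passed over all genes and 0 adjusted over the list alone. Actc1, cardiac alpha-actin, had 1056 and 891 FPKM in knockdown and 1367 and 1295 in control, and Mybph had 135 and 128 against 173 and 174. The list median was -0.12 in knockdown replicate 1 and -0.44 in knockdown replicate 2 relative to the control mean. It was therefore -0.12 without knockdown replicate 2 and -0.44 without knockdown replicate 1. With an estimated correlation the list was not called with all libraries or with either of these left out, so that test cannot tell them apart. Ttn, with 0.56, was a member in the opposite direction.

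The excitation-contraction coupling list fell, with a median of -0.18 over 19 members (camera adjusted p 0.00873), and the adjusted p was 0.583 with an estimated correlation. Its member Jsrp1 had -0.44 and its member Casq1, the calcium store protein, had 0.91. The list of neuromuscular junction and muscle metabolism genes fell, with a median of -0.15 over 21 members (camera adjusted p 0.00292), and the adjusted p was 0.583 with an estimated correlation. Chrnd, an acetylcholine receptor subunit, had -0.31 and Pgam2 had -0.45, which was -0.25 without knockdown replicate 2. Without knockdown replicate 2 the medians of these lists were -0.10 and -0.03, with camera adjusted p-values of 0.294 and 0.4997. With length, GC and level trends removed the camera adjusted p of the neuromuscular junction list was 0.0653, and without control replicate 2 that of the coupling list was 0.0758. In each of these lists 0 members passed over all genes and 0 adjusted over the list alone.

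Myoblast fusion genes had a median of 0.07 over 19 members (camera adjusted p 0.841). Over all genes 0 passed, and adjusted over the list alone Mymk, the fusion protein myomaker, was lower (-0.46) and Jam2 was higher (0.84). The Myod1 neighbourhood list had a median of 0.09 over 10 members (camera adjusted p 0.837), with a test direction opposite to its median, and its member Otog had -0.68. Without knockdown replicate 2 that median was -0.12, and without control replicate 2 it was 0.06.

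**Figure D2:**
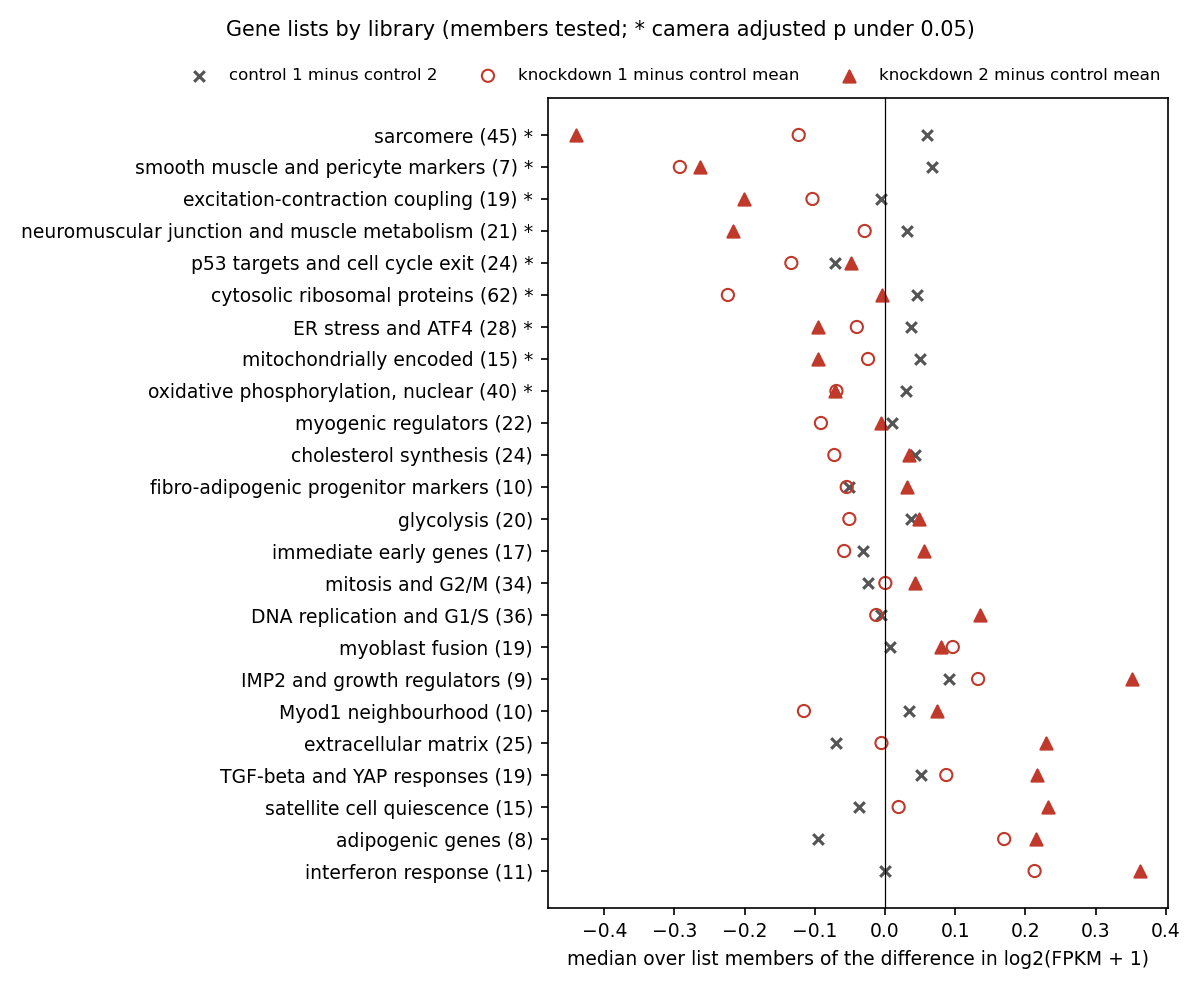
Median over the tested members of each list of the difference in log2(FPKM + 1), on the horizontal axis, for each knockdown library against the control mean and for control 1 against control 2. An asterisk marks the 9 lists with a camera adjusted p under the threshold, all to the left of 0 by their fitted median, and the knockdown libraries stand apart for sarcomere genes (-0.12 and -0.44) and ribosomal proteins (-0.22 and -0.005).

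Cytosolic ribosomal protein genes fell as a list, with a median of -0.12 over 62 members and 56 of them negative (camera adjusted p 6.47e-08). The adjusted p was 0.617 with an estimated correlation. The median was -0.22 in knockdown replicate 1 and -0.005 in knockdown replicate 2, and without knockdown replicate 1 the camera adjusted p was 0.207. Over all genes 0 passed, and adjusted over the list alone Rps25 was lower, with 26.6 and 30.6 FPKM against 49.6 and 49.0. Rpl11 had 0.42.

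Genes of the respiratory chain encoded in the nucleus fell as a list, with a median of -0.08 over 40 members (camera adjusted p 0.00210), and the adjusted p was 0.583 with an estimated correlation. Over all genes 0 passed, and adjusted over the list alone Uqcrfs1, the iron-sulfur protein of cytochrome bc1, was lower, with 187 and 178 FPKM against 296 and 264. Its member Atp5a1 had -0.27. Mitochondrially encoded genes fell, with a median of -0.09 over 15 members (camera adjusted p 0.0102), and the adjusted p was 0.583 with an estimated correlation. Their members mt-Nd5 and mt-Co1 had -0.29 and -0.18, and 0 passed over all genes or adjusted over the list alone. Without knockdown replicate 2 the medians of these lists were -0.07 and -0.02, with camera adjusted p-values of 0.0710 and 0.226; without control replicate 1 they were 0.0656 and 0.116, and without control replicate 2 that of the mitochondrially encoded list was 0.0706. The calls of both lists also ended with quantile normalization (0.126 and 0.230) and with trends removed (0.263 and 0.0824), and that of the mitochondrially encoded list with limma without the trend (0.0890).

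Genes of ER stress and ATF4, which respond to unfolded proteins and amino acid shortage, fell as a list, with a median of -0.11 over 28 members (camera adjusted p 0.00210). The adjusted p was 0.583 with an estimated correlation, and without knockdown replicate 2 the median was -0.04, with a camera adjusted p of 0.294. Without control replicate 2 the median was -0.07. Slc3a2 had 125 and 115 FPKM against 179 and 162, and Asns had 166 and 159 against 241 and 201. The p53 and cell cycle exit list fell, with a median of -0.13 over 24 members (camera adjusted p 0.0455), and the adjusted p was 0.583 with an estimated correlation. Its call ended without knockdown replicate 1, knockdown replicate 2 or control replicate 2, with camera adjusted p-values of 0.106, 0.181 and 0.347, and without knockdown replicate 1 its median was -0.05. It also ended with quantile normalization (0.126), no filter (0.0946), the filter at 5 FPKM (0.0634), limma without the trend (0.101) and trends removed (0.0992). Cdkn1a, the inhibitor p21, had 384 and 347 FPKM in knockdown against 472 and 459 in control, a log2 fold change of -0.35 with an adjusted p of 0.566, and Ccng1 had -0.30. In both lists 0 members passed over all genes and 0 adjusted over the list alone.

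Smooth muscle and pericyte markers fell as a list, with a median of -0.21 over 7 members (camera adjusted p 0.00177), and the adjusted p was 0.583 with an estimated correlation. Without control replicate 1 the camera adjusted p was 0.0589. Over all genes 0 passed, with a limma adjusted p of 0.607 for both Mcam and Acta2. Adjusted over the list alone Mcam and Acta2 were lower. Mcam lay near the filter, with 0.826 and 0.570 FPKM in knockdown against 2.22 and 1.94 in control. Acta2, smooth muscle actin, stood at 2623 ± 66.6 FPKM against 3093 ± 102 (SD, n = 2). Fibro-adipogenic progenitor markers had a median of -0.01 over 10 members (camera adjusted p 0.288), and their members Islr and Col1a1 had -0.59 and -0.51. The list median was 0.03 and -0.05 without knockdown replicates 1 and 2, and 0.04 and -0.04 without control replicates 1 and 2, and Islr and Col1a1 had -0.37 and -0.31 without knockdown replicate 2. Markers of endothelial cells, macrophages and Schwann cells had 2, 2 and 4 members above the filter, and osteogenic and chondrogenic genes had 4, so these lists were not tested; the highest mean levels were 5.19 FPKM for Eng, 1.68 for Cd14, 38.3 for Pmp22 and 468 for Spp1.

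Genes of the cell cycle did not pass as lists. DNA replication and G1/S genes had a median of 0.06 over 36 members (camera adjusted p 0.695), and mitosis and G2/M genes had 0.04 over 34 members (camera adjusted p 0.703). The G1/S median was 0.13 and -0.01 without knockdown replicates 1 and 2 and -0.0062 without control replicate 1, and the G2/M median was 0.00042 without knockdown replicate 2. The members with the lowest p went both ways, with Gins1 at -1.05, Orc1 at 0.82, Bub1b at -0.60 and Anln at 0.51. Ccnd1 had a log2 fold change of 0.16, which was 0.40 and -0.08 without knockdown replicates 1 and 2. Growth regulators linked to IMP2 had a median of 0.09 over 9 members (camera adjusted p 0.288), with Igfbp5 at 0.62. That median was 0.35 and 0.13 without knockdown replicates 1 and 2, and 0.13 and 0.39 without control replicates 1 and 2. Myc had 55.8 and 76.7 FPKM in knockdown against 49.8 and 50.7 in control, a log2 fold change of 0.37 with an adjusted p of 0.698. The Myc value was 0.60 and 0.15 without knockdown replicates 1 and 2. Nras had 0.09, in a range of 0.04 to 0.13 with 1 library left out. Igf2bp2, which codes for IMP2, had 0.548 and 0.252 FPKM against 0.215 and 0.624, below the filter and not tested.

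The other lists did not pass either. The interferon response list had a median of 0.32 over 11 members (camera adjusted p 0.0970), with 6 members above both controls and Bst2 at 0.32, which was 0.16 without control replicate 1. Without knockdown replicate 1 its median was 0.36, with a camera adjusted p of 0.0378. Satellite cell quiescence genes had a median of 0.17 over 15 members (camera adjusted p 0.288), with 0.02 in knockdown replicate 1 and 0.23 in knockdown replicate 2 relative to the control mean, and 0.08 without control replicate 1. Over all genes 0 passed, and adjusted over the list alone Cd34, a surface marker of quiescent satellite cells, was higher, with 4.52 and 4.62 FPKM against 1.36 and 1.17, while Fgfr4 had -0.31. Adipogenic genes had a median of 0.25 over 8 members (camera adjusted p 0.288), with 0 past the threshold over all genes. Adjusted over the list alone Pparg (1.02) and Plin2 (0.40) were higher. Pparg lay near the filter, with 2.07 and 1.61 FPKM in knockdown against 0.298 and 0.504 in control. Extracellular matrix genes had a median of 0.13 over 25 members (camera adjusted p 0.288), with 0 over all genes and Lox (0.73) and Tnc (0.73) higher adjusted over the list alone. The matrix median was 0.23 and -0.0051 without knockdown replicates 1 and 2 and 0.02 without control replicate 2, and the adipogenic median was 0.16 without control replicate 2.

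TGF-beta and YAP responses had a median of 0.15 over 19 members (camera adjusted p 0.777), with 0 over all genes and Thbs1 higher (0.66) adjusted over the list alone, and Cyr61 had -0.34. Its median was 0.22 and 0.09 without knockdown replicates 1 and 2. Immediate early genes had a median of 0.02 over 17 members (camera adjusted p 0.777) with a test direction opposite to it, Egr1 at -0.51 and Egr2 at 0.78. Their median was 0.06 and -0.06 without knockdown replicates 1 and 2, and -0.09 and -0.0075 without control replicates 1 and 2. Cholesterol synthesis genes had a median of -0.02 over 24 members (camera adjusted p 0.288), with Hsd17b7 at 0.43 and Cyp51 at -0.22, which was -0.13 without control replicate 1. Their median was 0.03 and -0.07 without knockdown replicates 1 and 2, and -0.01 and -0.08 without control replicates 1 and 2. The glycolysis list had a median of 0.007, a mean of -0.05 and a test direction of lower over 20 members (camera adjusted p 0.288). Its members Pfkp and Ankrd37 had -0.92 and -0.46. The list median was 0.05 and -0.05 without knockdown replicates 1 and 2, and -0.02 without control replicate 2.

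**Figure D3:**
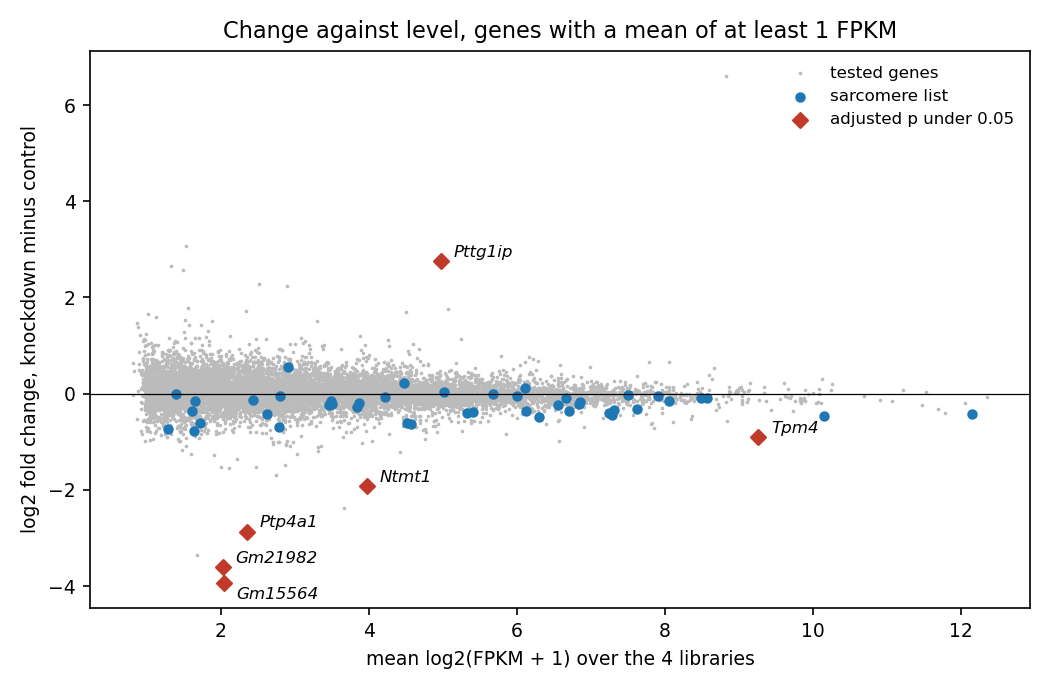
Log2 fold change, knockdown minus control, on the vertical axis against the mean log2(FPKM + 1) over the 4 libraries on the horizontal axis, for the 10900 tested genes. The 6 named genes past the threshold lie away from the bulk, and 41 of the 45 sarcomere genes lie below 0.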

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

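Summed overlapping rows and removed trends were tests chosen after the data were seen. Of the comparisons of named genes and of lists with their alternatives, 887 and 311 kept direction and side of the threshold. A further 20 and 43 lost the call, 3 and 1 gained it, and 2 and 25 reversed. The cause was not tested unless stated. The replicate block, limma without the trend and the filters leave a gene's fold change as it was. Fry and camera with an estimated correlation keep the list median, so direction could not change there. Most of these genes and lists were not called in the reported fit, so a kept result was mostly one not called in both. Against 5 lower genes in the reported fit, limma without the trend called 3, summed overlapping rows 3, a further threshold of 1 on the absolute log2 fold change 4, which Tpm4 at -0.90 did not reach, and no filter 0; with no filter 24969 genes were tested, 1508 had an unadjusted p under 0.05, and 0 were higher. Against 1 higher gene, median ratio scaling, a pseudocount of 0.1 and removed trends each called 2, adding Nfe2l1. With 1 library left out, higher genes ranged from 2 to 4, lower genes from 2 to 11 and lists called from 3 to 8; the 15 genes called without knockdown replicate 1 included all 6. Against 9 lists, removed trends called 5, quantile normalization 6, the filter at 5 FPKM and limma without the trend 7 each, no filter and unshared members 8 each, an estimated correlation 0 and fry 0 for movement one way. For change in either direction fry called 7 lists, of which camera had called 1, smooth muscle and pericyte markers; the others were quiescence, fusion, G1/S, TGF-beta and YAP, extracellular matrix and adipogenic genes (lowest adjusted p 0.0246).

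The labels do not say whether equal replicate numbers mark paired samples. The differences between replicates 1 and 2 in the groups did not correlate across genes (-0.021), which cannot exclude pairing. With the number as a replicate block 2 lower genes, 1 higher gene and 9 lists were called. Ptp4a1, Ntmt1 and Tpm4 lost the call (limma adjusted p 0.0871, 0.0871 and 0.135), and the block changed no other call.

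Reversals were in results not called, except Ptp4a1, which was 0.104 when its rows were summed. Immediate early genes took medians of -0.042 with quantile normalization, -0.013 with median ratio scaling, -0.031 with the filter at 5 FPKM, -0.019 with trends removed and -1.7e-05 with unshared members. Glycolysis took -0.0016 with quantile normalization, -0.022 with median ratio scaling and -0.0015 with no filter, where IMP2 took -0.0029 and fibro-adipogenic markers 0.036. The Myod1 neighbourhood took -0.056 with the filter at 5 FPKM, and myogenic regulators 0.0087 with unshared members. With 1 library left out, the ranges were -0.087 to 0.055 for immediate early genes, -0.051 to 0.048 for glycolysis, -0.055 to 0.040 for fibro-adipogenic markers, -0.12 to 0.12 for the Myod1 neighbourhood, -0.077 to 0.034 for cholesterol synthesis, -0.013 to 0.13 for G1/S, -0.0051 to 0.23 for extracellular matrix, -0.091 to 0.0056 for myogenic regulators and -0.077 to 0.40 for Ccnd1. At this depth and with 2 samples per group, changes of 2-fold or less were mostly out of reach, with 34.4% of 2-fold changes recovered in simulated data. Those data held 200 changed genes and gave 86.3 calls on average, against 6 here. More calls loosen the adjusted threshold, so recovery in the real data can be lower.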

Other observations

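The counts over splits and single libraries, the shared exons, the summed loci, the transcript lengths of Gm15564, Pttg1ip and Ntmt1, the removed trends and the readings of the sarcomere and ribosomal lists were tests chosen after the result was seen.

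Single libraries also held large departures, given here as values. Among 6373 rows with a mean of at least 5 FPKM, and with values under 1 FPKM raised to 1, 10 stood more than 4-fold above or below all other libraries in knockdown replicate 2, 7 in knockdown replicate 1, 3 in control replicate 1 and 3 in control replicate 2. Gpx1, a glutathione peroxidase, had 179 FPKM in knockdown replicate 2 and 16.7 to 20.5 in the others, and Bola1 had 1.54 in knockdown replicate 2 and 13.5 to 16.0 in the others. Both knockdown libraries stood more than 4-fold apart from both controls for 6 genes, among them Nfe2l1 and Zfp568, and the other ways of pairing the libraries gave 4 and 2 such genes.

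The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. The real split called 6 genes and the highest of the others 4, so 1 of the 3 splits gave as many. For gene lists the real split called 9 and the highest of the others 2, again 1 of the 3. At an unadjusted p under 0.05 the real split gave 772 genes and the others 337 and 406.

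The 6 called genes may in part reflect how fragments were assigned to annotated rows and transcripts. For Ptp4a1 the sum of its rows had a log2 fold change of 0.104 (95% interval -0.21 to 0.42), which leaves out the -0.56 that would result if the called row alone had changed. Gm21982 shares 94.3% of its exonic bases, and the interval of its summed locus, -0.40 to 0.32, holds both 0 and the -0.24 of a change in that row alone, so that a shift of fragments and a change of Gm21982 cannot be told apart. Pttg1ip, Gm15564, Ntmt1 and Tpm4 share at most 6.08% of their exonic bases with other rows, which argues against shared exons for these genes, and Gm15564 has transcripts that differ only 1.36-fold in length, which argues against a change of isoform. A change of isoform stays open for Tpm4, whose transcripts differ 5.93-fold in length against a fitted 1.87-fold change, and for Pttg1ip and Ntmt1, where the lower length ratio was 3.12 and neither ratio reached the fitted change; an effect of the siRNA stays open and was not tested apart from these.

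The lower sarcomere list had a median of -0.26 after trends with length, GC content and level were removed, against -0.22 before. These medians argue against the trends as its whole cause. The camera adjusted p after removal was 6.9e-07 with the preset correlation, which can call unshifted lists that share a library effect. Whether the lower sarcomere list rests on knockdown replicate 2 stays open. The median was -0.123 without that library and -0.440 without knockdown replicate 1, with 1 knockdown library left each time. With an estimated correlation the list was not called in either fit, so that test cannot tell the libraries apart. Cultures that differed in how far they had differentiated, whatever the siRNA, could give the same pattern. The median difference of knockdown replicate 2 from knockdown replicate 1 was -0.365, larger in size than the -0.22 between the groups, and the adjusted p was 0.583 with an estimated correlation. An effect of the knockdown stays open beside it.

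The lower ribosomal protein list may come from knockdown replicate 1, since the list median without that library was -0.0046 (camera adjusted p 0.207) and without knockdown replicate 2 it was -0.22. No biological explanation was tested for it.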
